A study of Mus musculus with 4 samples.

How the data were processed

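Single-cell RNA was measured in 4 libraries of mouse cells enriched for the O4 surface antigen, which marks the oligodendrocyte lineage from late precursors onward. There was 1 library each from control spinal cord and knockout spinal cord at postnatal day 10, and from control brain and knockout brain at postnatal day 14. Knockout animals carried Cre recombinase at the Cnp locus together with floxed Mtor alleles, and controls carried the floxed alleles alone. Cells were enriched on magnetic columns and captured with the 10x Genomics 3' v2 chemistry, per the labels' protocols. How many animals were pooled in a library is not given in the sources used here.

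The deposited values were counts of unique molecular identifiers (UMIs) per gene and barcode, one whole number for each, with no normalization by the authors. Per the submitters' processing notes, the tools included bcl2fastq 2.20, Cell Ranger 3.0.2 and Seurat 3.0.2, with genome build mm10. Which version of the gene annotation was used upstream is not given in the sources used here. Each file listed 31053 genes by Ensembl identifier and symbol. The lowest barcode total in each library was 500 UMIs, and no barcode lists beyond those filtered by the authors were used here. Coordinates were taken from GENCODE vM21, an annotation of the same build, and are 1-based.

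Barcodes were kept with at least 500 UMIs, at least 300 genes and under 10% mitochondrially encoded counts. Doublets were scored within each library against simulated pairs, with 1 simulated pair per barcode, 1000 variable genes, 20 principal components and 40 neighbours. The highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes, which took 8.43% of the cord control, 10.0% of the cord knockout, 15.4% of the brain control and 17.4% of the brain knockout barcodes. The kept barcodes of all 4 libraries were clustered together on 2000 variable genes, 30 principal components and a graph of 15 neighbours with the Leiden method at resolution 1.0. Genes of the fixed lists (other than myelin proteins and oligodendrocyte transcription factors), sex-linked, ribosomal and mitochondrially encoded genes were left out of the clustering.

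Each of the 38 clusters took the name of the cell type with the most fixed markers among its top 10 genes by fold over the other clusters, provided that at least 3 of that type's markers reached 20 CPM, the usual scaling of a count to the UMI total. Marker sets were fixed for 19 cell types. In this way 36 clusters were named, while 2 with low UMI totals and no marker among their top 10 genes stayed unnamed. A cord cluster that scored alike for precursor and committed precursor markers was divided again at resolution 0.5, a step chosen after seeing the data. OPC-like denotes oligodendrocyte precursor clusters, premyelinating denotes committed precursors (COP) and newly formed oligodendrocytes (NFOL), and myelinating denotes myelin-forming (MFOL) and mature (MOL) oligodendrocytes. All names were rebuilt from markers and are not the authors' annotation.

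UMI counts were summed per library and class and scaled to CPM of that sum, with each gene given as a log2 ratio of CPM. With 1 library per group there is no replicate, so no test was made and no p-value is given, and every difference is between these libraries and not between conditions. Intervals are 95% intervals for counting error only, exact conditional binomial ones for ratios of counts and Clopper-Pearson ones for shares. For a list, the value is the median log2 ratio over members with at least 20 UMIs in the libraries compared. Its counting interval came from 2000 Poisson redraws of the member counts. Its percentile places it among 10000 random lists of the same size matched on mean expression, and describes these libraries only. Members are counted as higher or lower from 1.5-fold. A gene with no UMI in a group was set to 3 counts per group, which gives a bound.

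Results are given for 20 lists. Of these, 18 were fixed by name: cholesterol biosynthesis, SREBP pathway control, cholesterol transport and uptake, fatty acid and sphingolipid synthesis, myelin proteins, oligodendrocyte transcription factors, mTOR complexes and regulators, translation factors with other genes of the terminal oligopyrimidine (TOP) class, glycolysis and HIF targets, ATF4 and amino acid response, lysosome and TFEB targets, endoplasmic reticulum chaperones, p53 targets, interferon and MHC class I, immediate early and dissociation genes, Hox genes, forebrain and midbrain positional genes, and sex-linked genes. The other lists were taken by symbol and hold the mitochondrially encoded genes and the cytosolic ribosomal protein genes. The symbol rule for ribosomal genes also takes in the S6 kinase genes Rps6ka3, Rps6kb1 and Rps6kb2 and the paralogs Rpl22l1 and Rps27rt, and it leaves out Rplp0.

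Genes were named by a fixed rule. Mtor and Cnp were given in every library and stage. From the cholesterol list every measured member was eligible, and from each other list the 4 with the highest mean CPM and the 2 with the largest absolute log2 ratio at 20 CPM or more. For the OPC-like and myelinating stages, the rule added the 10 genes with the highest and the 10 with the lowest mean log2 ratio for knockout against control and for brain against cord. These had to reach 50 CPM in the higher library and 100 UMIs in each pair, with a difference of at least 1.5-fold in the same direction in both pairs. Counts under 3 were set to 3 for this ranking, and markers, haemoglobin, sex-linked and mitochondrially encoded genes were left out of it. Sex-linked and Hox genes were given as label checks. Of the genes this rule names, those that also lead a cluster of the class they were measured in are not given.

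The groups, lists, markers, naming rule, thresholds and 11 alternative settings were fixed before the data were examined. The 11 settings were 2 other cell filters, doublets kept, 2 other clustering resolutions, list genes kept in clustering, each library clustered alone, scaling by the median of ratios, the mean of per-cell CPM, thinning of each cell to 1000 UMIs, and a minimum of 100 UMIs per list member. A further 7 were chosen after seeing the data. All genes here means those with at least 100 UMIs over the libraries compared. Between brain and cord their median was below 0 at every stage, so values for that comparison are also given relative to it.

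The calculation was tested on simulated counts for the cord knockout against the cord control, with 200 genes given known folds. In OPC-like sums (2523 genes), the 1.5-fold threshold was passed by 52% of genes given 1.5-fold and 100% of genes given 2-fold, and by 1.46% of genes given none. In myelinating sums (8874 genes), it was passed by 42% of genes given 1.5-fold and 96% of genes given 2-fold, and by 0.357% of genes given none. The simulated counts held counting error only, with no variation between animals or preparations. These rates thus do not say how often the real libraries pass the threshold without an effect of the knockout.

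Summed counts ran in python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, clustering in igraph 0.11.9 with leidenalg 0.10.2, and plots in matplotlib 3.10.9. Raw reads, droplets below the authors' barcode filter and splice junctions were not analysed here.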

Results

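The 4 libraries held 10538 barcodes for control spinal cord, 12534 for knockout spinal cord, 19204 for control brain and 21701 for knockout brain. Their total UMI counts were 24772968, 27057319, 39879531 and 55798574 in that order. After filtering and doublet removal 8321, 9125, 14584 and 15865 barcodes were kept, with median totals of 1535, 1970, 1339 and 1677 UMIs. Each group was 1 library, so no difference has a replicate check, and intervals are 95% intervals that cover counting error only. The series asks what loss of mTOR, a kinase that controls growth and metabolism, does to oligodendrocyte-lineage cells in brain and spinal cord, with cholesterol synthesis as a named interest. Region cannot be told apart from age, because cord was taken at postnatal day 10 and brain at postnatal day 14. Loss of mTOR cannot be told apart from Cre at the Cnp locus, which controls lacked.

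Oligodendrocyte-lineage cells numbered 5024 in the cord control, 6660 in the cord knockout, 5483 in the brain control and 5086 in the brain knockout. The other kept cells included astrocytes in all 4 libraries (473, 758, 2946 and 3244) and, in brain, microglia (1766 and 1773), endothelial cells (1169 and 1249), mural cells (990 and 945), choroid plexus cells (410 and 349) and immature neurons (368 and 739). Unnamed clusters held 30.1% of kept cord control barcodes, 15.1% of cord knockout, 2.70% of brain control and 5.37% of brain knockout barcodes. They were the largest class in cord that was given no stage. The main cord one was led by Mbp, so it may hold lineage cells. The nuclear RNA Malat1 took 7.56% and 8.69% of all UMIs in the cord libraries and 22.6% and 20.2% in the brain libraries.

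Mtor, the targeted gene (ENSMUSG00000028991, mm10 chromosome 4, 148448611 to 148557683), was lower in both knockout libraries in premyelinating and myelinating cells. In myelinating cells it stood at 19.1 CPM in the cord control and 7.54 CPM in the cord knockout (log2 ratio −1.34, −1.72 to −0.97; 173 and 91 UMIs). In brain the values were 12.7 and 4.97 CPM (−1.35, −2.01 to −0.73; 74 and 31 UMIs). In premyelinating cells it stood at 25.5 and 15.03 CPM in cord (−0.76, −1.16 to −0.38) and at 18.2 and 7.72 CPM in brain (−1.24, −1.70 to −0.80). In OPC-like cells the counts were 16 and 9 UMIs in cord (−0.83, −2.19 to 0.44) and 12 and 20 UMIs in brain (−0.00, −1.11 to 1.16), so no difference was detectable at this depth. The deleted exons are not given in the sources used here, and a 3' tag outside the deleted part checks nothing, so these values do not measure recombination.

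Cnp, the gene at the driver locus (ENSMUSG00000006782, chromosome 11, 100574904 to 100591729), was lower in both knockout libraries at every stage. In myelinating cells it stood at 8740 CPM in the cord control and 3870 CPM in the cord knockout (−1.18, −1.19 to −1.16), and at 3308 and 1791 CPM in brain (−0.89, −0.92 to −0.85). In premyelinating cells the log2 ratio was −1.04 (−1.06 to −1.01) in cord and −0.76 (−0.80 to −0.72) in brain, and in OPC-like cells −1.45 (−1.54 to −1.35) and −0.41 (−0.62 to −0.21). The OPC-like values may include RNA from other cells. Myelinating markers stood there at 49.2% and 46.8% of their library level in the cord control and knockout.

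Sex-linked and positional genes were read as checks of the labels. Xist, which is transcribed from the inactive X chromosome, had 3131 UMIs in myelinating cells of the cord control and 0 in each of the other 3 libraries, while the Y-linked gene Ddx3y had 734, 1057, 299 and 278 UMIs in cord control, cord knockout, brain control and brain knockout. The cord control thus held cells of both sexes. Hoxd8, a positional gene of the spinal cord, had 344 and 529 UMIs in myelinating cells of the cord libraries and 0 and 1 in the brain libraries. Forebrain and midbrain positional genes in premyelinating cells went the other way, with all 3 measured members higher in the brain control than in the cord control (median log2 ratio 3.25 relative to all genes, 2.56 to 3.77).

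In the spinal cord, genes for cholesterol synthesis were lower in the knockout library at all 3 stages, and the lists of fatty acid and sphingolipid synthesis and of myelin proteins had medians below 0 in myelinating cells, with 6 of 20 and 1 of 11 members lower by at least 1.5-fold. Genes for ribosomal proteins (61 of 87) and translation factors (7 of 15) were higher in the same myelinating cells. Of the 20 cholesterol biosynthesis genes, all 20 lay below 0 in OPC-like and in myelinating cells, and 11 of them by at least 1.5-fold at each of these stages. The list median was −0.63 in OPC-like cells (−0.76 to −0.48), −0.49 in premyelinating cells (−0.55 to −0.45; 6 of 20 lower by at least 1.5-fold) and −0.60 in myelinating cells (−0.63 to −0.57). Each of these medians lay at percentile 0 of the matched random lists.

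In myelinating cord cells, Hmgcs1, the enzyme that makes HMG-CoA (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), stood at 2542 CPM in the control and 1486 CPM in the knockout (−0.77, −0.80 to −0.75). Fdps, which makes farnesyl pyrophosphate (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), stood at 840 and 484 CPM (−0.79, −0.84 to −0.75). Fdps is also among the leading genes of the main unnamed cord cluster. Lss, the cyclase that makes lanosterol, stood at 195 and 97.5 CPM (−0.997, −1.10 to −0.89). Myelinating cord cells came from cluster 9 (MFOL) and cluster 5 (MOL), and the list median was −0.68 within the first and −0.60 within the second.

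In OPC-like cord cells, Hmgcs1 stood at 1314 CPM in the control and 611 CPM in the knockout (−1.10, −1.26 to −0.95), Fdps at 563 and 290 CPM (−0.96, −1.19 to −0.72) and Lss at 77.7 and 23.0 CPM (−1.76, −2.60 to −0.98). Beside these values, Mbp, a myelin protein gene, stood at 63911 CPM in OPC-like cells of the cord control and at 55012 CPM in macrophage-lineage cells of the same library. The summed cholesterol list stood at 5003 and 3006 CPM in OPC-like cells of the cord control and knockout and at 3537 and 1897 CPM in their macrophage-lineage cells. The myelin protein list was also lower in OPC-like cord knockout cells (−0.55, −0.61 to −0.48; 4 of 11 lower, 1 higher).

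**Figure D1:**
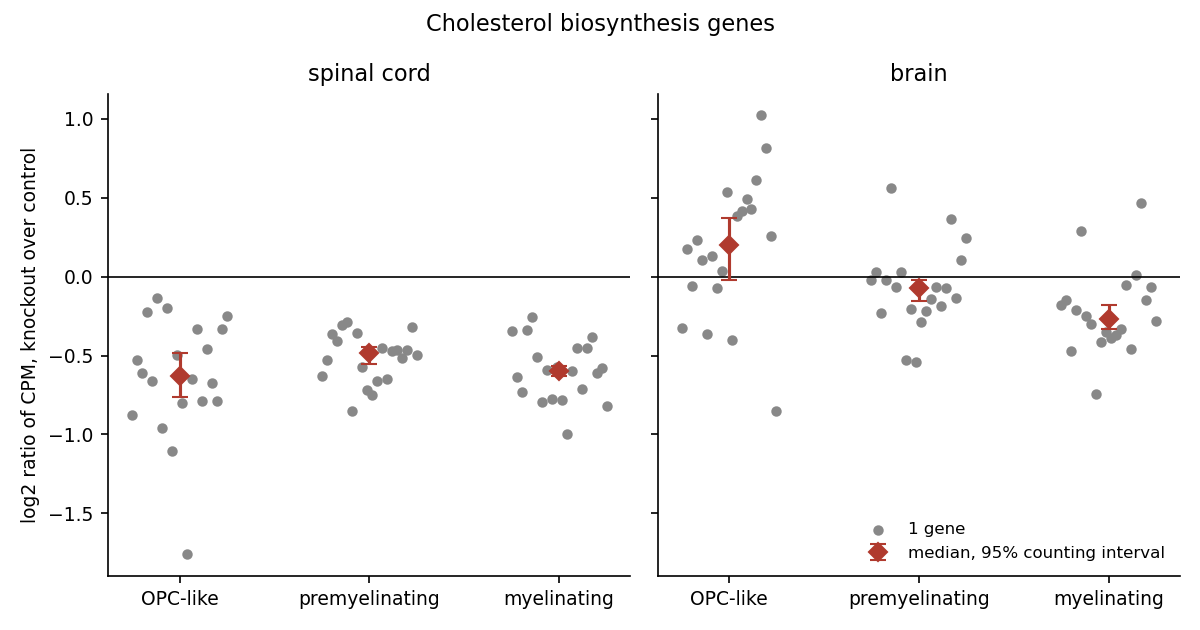
Log2 ratio of CPM, knockout over control, for each of the 20 cholesterol biosynthesis genes (points) at each of 3 stages, in spinal cord and in brain, with the list median as a diamond and its 95% counting interval as a bar. All 20 genes lie below 0 in OPC-like and myelinating cord cells, where the medians are −0.63 and −0.60, while the brain medians are 0.20 in OPC-like cells, where 3 of 13 alternative settings turned the direction, and −0.27 in myelinating cells.

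The fatty acid and sphingolipid list in myelinating cord cells had a median of −0.41 (−0.50 to −0.38, percentile 0), with 6 of 20 members lower by at least 1.5-fold and none higher. Scd1, a stearoyl-CoA desaturase, stood at 53.8 and 18.2 CPM (−1.56, −1.80 to −1.33) and its paralog Scd2 at 2404 and 1414 CPM (−0.77, −0.79 to −0.74). Acss2, which makes acetyl-CoA from acetate, stood at 152 and 70.1 CPM (−1.11, −1.24 to −0.99), and Acly, which makes it from citrate, at 222 and 135 CPM (−0.72, −0.81 to −0.62). In OPC-like cord cells the same list stood at −0.23 (−0.50 to −0.17; 5 of 20 lower). SREBP pathway control genes showed no such difference in myelinating cells (−0.03, −0.21 to 0.03). Cholesterol transport genes stood at −0.18 (−0.23 to −0.06; 3 of 14 higher, 1 lower), and among the higher ones was Apoe, a lipid carrier (86.0 and 254 CPM; 1.56, 1.45 to 1.68).

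Myelin protein genes in myelinating cord cells had a median of −0.50 (−0.52 to −0.48, percentile 0 of matched lists), with 1 of 11 lower by at least 1.5-fold. Mbp stood at 41362 CPM in the control and 32704 CPM in the knockout (−0.34, −0.35 to −0.33). Oligodendrocyte transcription factors had a median of 0.35 (0.21 to 0.47, percentile 99.3), with 6 of 14 higher. Among them Tcf7l2 stood at 23.5 and 47.8 CPM (1.02, 0.80 to 1.26), a ratio of 0.70 when doublets were kept.

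Cytosolic ribosomal protein genes had a median of 0.70 in myelinating cord cells (0.68 to 0.71, percentile 100), with 61 of 87 higher by at least 1.5-fold and 1 lower. Rps28 stood at 787 and 1751 CPM (1.15, 1.12 to 1.19) and Rpl41 at 1950 and 3118 CPM (0.68, 0.65 to 0.70). Translation factors and other TOP genes, whose messages carry the same 5' motif, had a median of 0.56 (0.51 to 0.63; 7 of 15 higher, none lower). Eef1a1, the elongation factor that delivers tRNA, stood at 1659 and 3280 CPM (0.98, 0.96 to 1.01). In OPC-like cord cells the ribosomal median was 0.24 (0.21 to 0.27; 1 of 83 higher, 2 lower).

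Of the remaining lists in myelinating cord cells, immediate early and dissociation genes stood at 0.67 (0.16 to 1.07; 5 of 8 higher, 1 lower) and Hox genes at 0.38 (0.07 to 0.54; 4 of 15 higher). Immediate early genes were also higher in OPC-like cord cells (1.09, 0.40 to 1.61; 5 of 7), among them the transcription factor genes Egr1 (30.6 and 89.5 CPM; 1.55, 0.86 to 2.28) and Junb (3 and 19 UMIs; 2.67, 0.90 to 5.07). Interferon and MHC class I genes had a median of −0.50 (−0.93 to −0.09; 2 of 10 higher, 4 lower), while H2-D1, a class I heavy chain gene, stood at 5.18 and 20.9 CPM (2.01, 1.56 to 2.49). The lists of mTOR complexes and regulators (−0.04), glycolysis and HIF targets (−0.15), ATF4 and amino acid response (−0.07), lysosome and TFEB targets (−0.06), endoplasmic reticulum chaperones (0.07), p53 targets (−0.05), sex-linked genes (0.15) and mitochondrially encoded genes (−0.16) stood closer to 0. Within the mTOR list, Ddit4, an inhibitor of mTOR complex signalling, stood at 190 and 74.6 CPM (−1.35, −1.47 to −1.23).

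In the brain, the median of the cholesterol list lay slightly below 0 in myelinating cells of the knockout library. Its direction in OPC-like cells depended on the settings. The median was −0.27 in myelinating cells (−0.33 to −0.18, percentile 0; 1 of 20 lower by at least 1.5-fold, 3 above 0) and −0.07 in premyelinating cells (−0.15 to −0.02, percentile 7.27; none past 1.5-fold). In OPC-like cells it was 0.20 (−0.02 to 0.37; 3 of 20 higher, 1 lower), a direction that turned in 3 of 13 alternative settings, with values from −0.23 to 0.59. In myelinating brain cells, Hmgcs1 stood at 988 and 742 CPM (−0.41, −0.47 to −0.36), Fdps at 164 and 133 CPM (−0.30, −0.44 to −0.17) and Idi1, an isomerase of the same pathway, at 204 and 156 CPM (−0.39, −0.51 to −0.26). Pmvk, a mevalonate pathway kinase, went the other way, at 102 and 142 CPM (0.47, 0.32 to 0.62). In OPC-like brain cells Hmgcs1 stood at 131 and 134 CPM (0.04, −0.29 to 0.37). Outside the lineage, the list median in brain was −0.26 in microglia (−0.40 to −0.01) and −0.03 in astrocytes (−0.12 to 0.05). A value like that of myelinating cells was thus also seen in microglia.

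Fatty acid and sphingolipid genes in myelinating brain cells had a median of −0.14 (−0.23 to −0.07; 3 of 19 lower, none higher). Acss2 stood at 72.4 and 43.5 CPM (−0.73, −0.96 to −0.51), Acly at 125 and 77.3 CPM (−0.70, −0.87 to −0.53) and Scd2 at 1695 and 1077 CPM (−0.65, −0.70 to −0.61). Myelin protein genes stood at −0.11 (−0.12 to −0.09; 1 of 12 lower). The ribosomal protein list had a median of −0.18 (−0.20 to −0.16), with 6 of 86 members lower by at least 1.5-fold and none higher. Among its members, Rpl41 stood at 5120 and 3344 CPM (−0.61, −0.64 to −0.59) and Rps28 at 2264 and 1960 CPM (−0.21, −0.24 to −0.17). The ribosomal median in OPC-like brain cells was −0.33 (−0.36 to −0.31; 14 of 82 lower, 2 higher).

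The mitochondrially encoded list had medians above 0 in the brain knockout library. They were 0.24 in myelinating cells (0.20 to 0.26), where 2 of 13 members were higher by at least 1.5-fold and 1 lower, and 0.35 in OPC-like cells (0.31 to 0.42). In OPC-like cord cells the median was 0.07 (0.02 to 0.11). Before filtering, the median mitochondrial share of a barcode was 2.73% in the brain control and 3.94% in the brain knockout, and 284 and 1100 barcodes failed the mitochondrial filter. In brain, mt-Nd3 stood at 667 and 1165 CPM in myelinating cells (0.80, 0.75 to 0.86) and mt-Atp6 at 4337 and 8538 CPM in OPC-like cells (0.98, 0.93 to 1.03). Endoplasmic reticulum chaperones stood at 0.17 in myelinating cells (0.10 to 0.33) and translation factors at 0.11 (0.01 to 0.18). For SREBP pathway control (−0.14), cholesterol transport (−0.06), transcription factors (−0.01), mTOR complexes and regulators (−0.17), glycolysis (−0.02), ATF4 response (0.06), lysosome (0.07), p53 targets (0.02), interferon (−0.02) and immediate early genes (0.04), the counting interval held 0, and for sex-linked genes the median was −0.26 (−0.46 to −0.01).

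**Figure D2:**
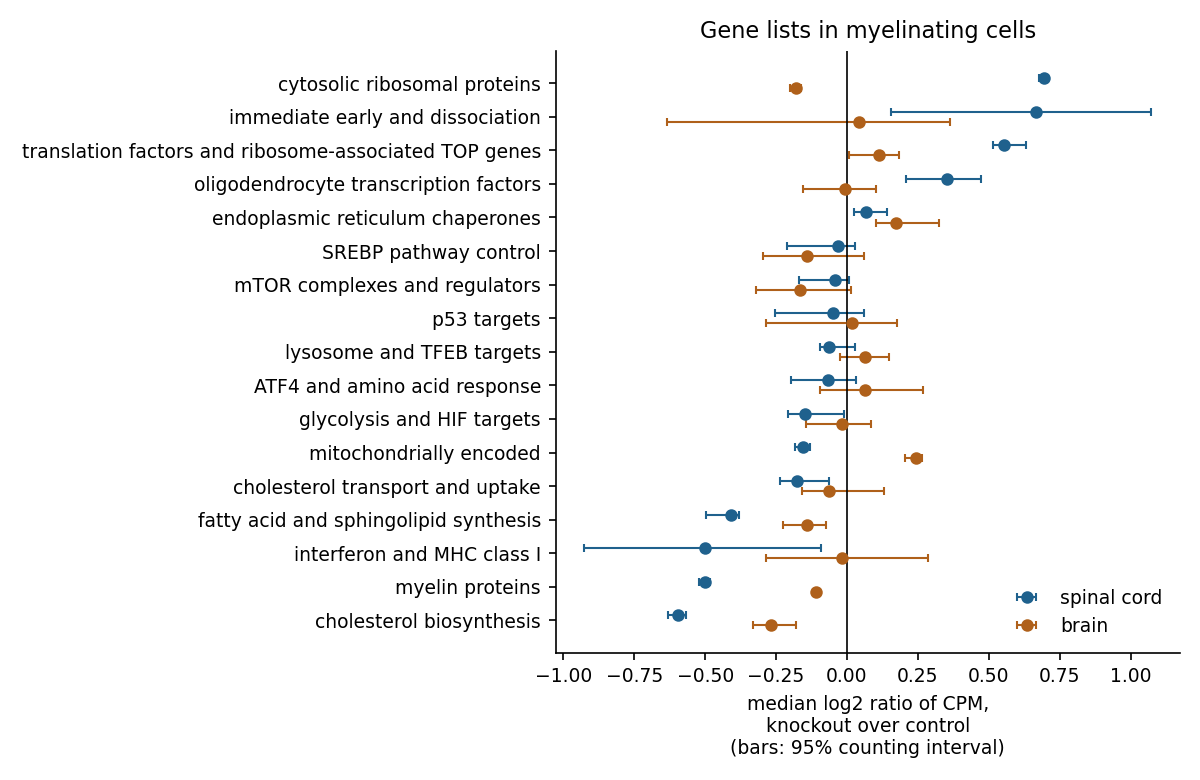
Median log2 ratio of CPM, knockout over control, in myelinating cells for 17 gene lists, with spinal cord in blue, brain in orange and 95% counting intervals as bars. Cholesterol biosynthesis lies below 0 in both regions (−0.60 and −0.27), while ribosomal protein genes lie at 0.70 in cord and −0.18 in brain.

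A few genes differed in the same direction in both regions. In myelinating cells 20 genes were higher and 18 lower by at least 1.5-fold in both knockout libraries, of 3074 that met the expression minimums, and in OPC-like cells 1 was higher and 5 lower of 1886. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) was higher at both stages in both regions. In brain it stood at 179 and 445 CPM in myelinating cells (1.31, 1.21 to 1.42) and at 944 and 2193 CPM in OPC-like cells (1.22, 1.11 to 1.33), and in OPC-like cord cells at 638 and 1222 CPM (0.94, 0.78 to 1.10). Apoe is abundant in astrocytes, where it stood at 6604 and 12644 CPM in brain and at 27998 and 30647 CPM in cord.

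Other genes higher in both knockout libraries in myelinating cells were Fam13c (ENSMUSG00000043259, chromosome 10, 70440481 to 70558736), with log2 ratios of 2.003 in cord (1.87 to 2.14) and 1.04 in brain (0.70 to 1.39), and Basp1, a membrane-associated growth cone protein (1.67 and 1.24). The tetraspanin gene Cd63 (1.44 and 0.97), the tubulin gene Tubb2b (1.27 and 1.09), the insulin-like growth factor receptor gene Igf1r (1.14 and 0.84) and the ribosomal stalk gene Rplp0 (1.02 and 0.96) met the same rule. Lower in both were the chemokine gene Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367; −2.90 in cord, −3.38 to −2.45, and −1.35 in brain, −1.50 to −1.20), the glutamate receptor gene Grm4 (−2.11 and −0.98), the matrix protein gene Mgp (−1.57 and −0.96) and Sesn3, an mTORC1 regulator of the sestrin family (−1.12 and −0.83). Cxcl12 is also among the leading genes of endothelial and mural clusters and Mgp of a fibroblast cluster. In OPC-like cells Tmsb10, an actin-binding thymosin (−0.68 and −0.76), and Ptges3, a chaperone cofactor (−0.72 and −0.74), were lower in both. Genes that lead a cluster of the same class are not given.

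The knockout ratio of the cholesterol genes was lower in spinal cord than in brain at all 3 stages. The median difference per gene, cord minus brain, was −0.80 in OPC-like cells (−1.08 to −0.55), −0.41 in premyelinating cells (−0.51 to −0.35) and −0.40 in myelinating cells (−0.45 to −0.32). Astrocytes gave −0.52 (−0.67 to −0.33) with free RNA left in, and in OPC-like cord cells the knockout ratio of the summed list, −0.73, lay no lower than the −0.90 of macrophage-lineage cells. With 1 library in each group this difference was not tested.

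Between the control libraries, cholesterol genes were lower in brain than in spinal cord at all 3 stages, most of all in OPC-like cells, and Hox genes were lower in brain. Over all genes the median log2 ratio of brain to cord was −0.20 in OPC-like, −0.62 in premyelinating and −0.72 in myelinating cells, and the values that follow are relative to it. The cholesterol list stood at −2.50 in OPC-like cells (−2.75 to −2.22; 19 of 20 lower by at least 1.5-fold), −1.001 in premyelinating cells (−1.07 to −0.91; 13 of 20; clusters 0 and 11 in brain, 6, 36 and 12 in cord) and −0.79 in myelinating cells (−0.87 to −0.68; 12 of 20). Between the knockout libraries the same medians were −1.45, −0.61 and −0.27. With free RNA left in, the control comparison in CPM stood at −1.74 in astrocytes, −1.77 in microglia, −2.26 in cycling cells and −1.96 in erythroid cells. The difference was thus not confined to the 3 stages. Relative to all genes these values were −1.32, −1.96, −2.75 and −2.02. The all-gene median itself was −0.41, 0.18, 0.48 and 0.06, over 4681, 1693, 1013 and 239 genes, so relative values cannot be ranked between classes. Unnamed barcodes stood at −2.38 in CPM and −1.30 relative to all genes. In cord these were mainly a cluster led by Mbp, which may hold lineage cells.

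In OPC-like cells Hmgcs1 stood at 131 CPM in brain and 1314 CPM in cord (relative log2 ratio −3.12, −3.41 to −2.85). Fdps, which also leads an unnamed cord cluster, stood at 49.4 and 563 CPM (−3.31, −3.78 to −2.87). OPC-like brain cells formed cluster 10, and OPC-like cord cells formed clusters 4 and 37. Before scaling to all genes, the summed cholesterol list had a log2 ratio of −2.63 in OPC-like cells (−2.74 to −2.52) and −2.25 in macrophage-lineage cells of the same control libraries (−2.40 to −2.10), and Mbp stood at 5712 CPM in OPC-like cells of the brain control against 63911 CPM in the cord control. In OPC-like cells the lists of myelin proteins (−1.96, −2.04 to −1.89; 10 of 11 lower), translation factors (−1.46, −1.63 to −1.19; 11 of 15 lower, 2 higher), ATF4 response (−1.30, −1.78 to −0.64; 6 of 9 lower, 2 higher), glycolysis (−1.10, −1.45 to −0.76), lysosome (−1.08, −1.26 to −0.82) and fatty acid genes (−0.88, −1.40 to −0.74; 16 of 20 lower) were lower in brain. The cholesterol transport list went the other way (0.48, 0.05 to 0.73, with 7 of 14 higher and 2 lower), at 0.28 in CPM. The ribosomal protein list had a median of 0.29 (0.27 to 0.35), at 0.09 in CPM. Of its 82 members 20 were higher, 15 lower and 47 between, so the list had no common direction. In microglia of the same control libraries the all-gene median was 0.18, so values relative to it are lower than in CPM. The cholesterol list there stood at −1.77 in CPM and −1.96 relative to all genes. Relative to all genes, the other lists there stood at −1.95 for myelin proteins, −1.55 for translation factors, −1.79 for glycolysis, −1.85 for lysosome and −1.37 for fatty acid genes. Ntm, a neural cell adhesion gene that also leads an astrocyte cluster, stood at 2067 CPM in brain and 103 CPM in cord (4.52, 4.203 to 4.86), and the dendritic RNA Bc1, which leads an unnamed brain cluster, at 342 and 5.10 CPM (6.27, 4.90 to 8.15). Hox genes stood at −3.41 (−3.85 to −2.92; 3 measured).

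In myelinating cells, taken from cluster 8 (MFOL) in brain and clusters 9 and 5 (MFOL and MOL) in cord, Hmgcs1 stood at 988 CPM in brain and 2542 CPM in cord (−0.65, −0.69 to −0.61) and Fdps at 164 and 840 CPM (−1.64, −1.74 to −1.54). Gal3st1, the sulfotransferase that makes sulfatide, stood at 113 and 1014 CPM (−2.45, −2.56 to −2.33) and Mbp, which also leads an unnamed cord cluster, at 8204 and 41362 CPM (−1.62, −1.63 to −1.60). Ribosomal protein genes stood at 0.80 (0.77 to 0.83; 54 of 87 higher, 10 lower) relative to all genes and at 0.08 in CPM (0.06 to 0.11; 11 higher, 21 lower), with Rpl3 among the lower ones at 84.5 and 977 CPM (−2.81, −2.95 to −2.68), and translation factors at −0.95 (−1.07 to −0.65; 8 of 15 lower, 2 higher). Nmt1, an N-myristoyltransferase, stood at 364 and 31.5 CPM (4.24, 4.07 to 4.43), and Mt3, a metallothionein that also leads an astrocyte cluster, at 113 and 13.5 CPM (3.78, 3.50 to 4.07). Hox genes stood at −3.06 (−3.24 to −2.79; 8 of 8 lower) and fatty acid genes at −0.24 (−0.30 to −0.16; 6 of 19 lower). Myelin protein genes stood at 0.50 (0.48 to 0.53) and transcription factors at 0.58 (0.49 to 0.65) relative to all genes, and at −0.21 and −0.14 in CPM, so their direction depends on the scaling. The same holds for the lists of cholesterol transport (0.35 and −0.36), interferon (0.49 and −0.23), immediate early (0.49 and −0.23), mitochondrially encoded (0.18 and −0.54), mTOR (0.13 and −0.59) and sex-linked genes (0.11 and −0.60).

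**Figure D3:**
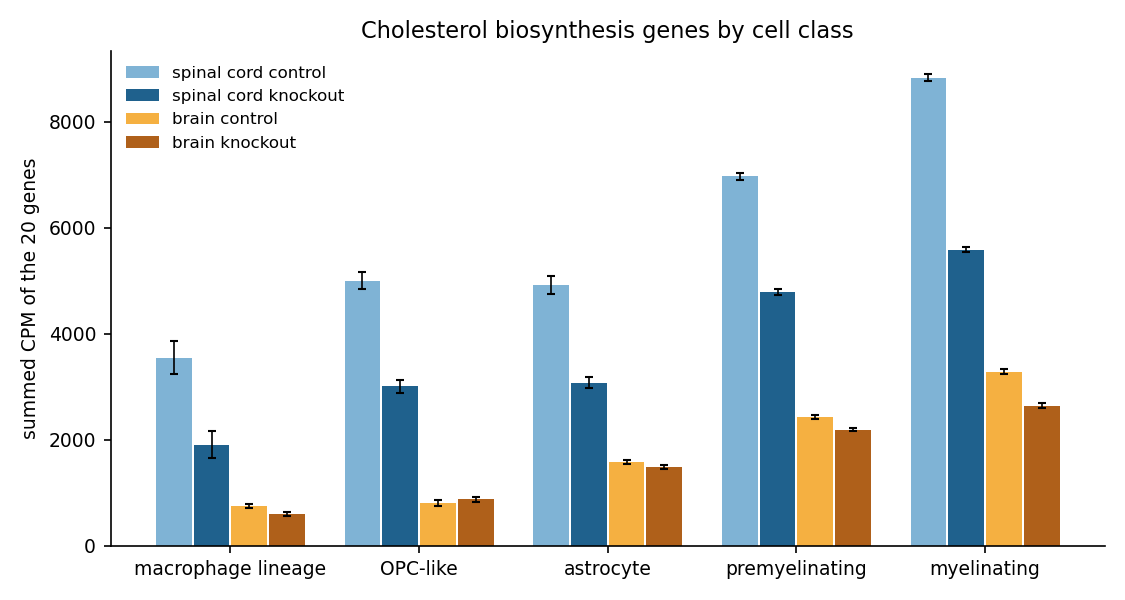
Summed CPM of the 20 cholesterol biosynthesis genes in macrophage-lineage, OPC-like, astrocyte, premyelinating and myelinating cells of the 4 libraries, with bars for the sums and lines for 95% counting intervals. The sum in myelinating cells is 8836 CPM in the cord control, 5587 in the cord knockout, 3282 in the brain control and 2644 in the brain knockout.

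OPC-like cells made up 14.9% of lineage cells in the cord control (14.0 to 15.96%), 12.7% in the cord knockout (11.96 to 13.6%), 17.4% in the brain control (16.4 to 18.4%) and 22.9% in the brain knockout (21.7 to 24.1%). Myelinating cells made up 34.6% (33.3 to 35.9%), 49.8% (48.6 to 51.0%), 20.7% (19.6 to 21.8%) and 22.0% (20.9 to 23.2%) in the same order, and premyelinating cells 50.4% (49.0 to 51.8%), 37.4% (36.3 to 38.6%), 61.9% (60.6 to 63.2%) and 55.1% (53.7 to 56.5%). MOL-like cells numbered 951 in the cord control and 1957 in the cord knockout, but 0 and 1 in the brain libraries. Selection for O4 on the columns can set these shares, and the unnamed cord barcodes, 30.1% in the control and 15.1% in the knockout, are outside them. Other settings put the OPC-like share at 9.97 to 29.8% in the cord control, 9.90 to 22.0% in the cord knockout, 6.67 to 19.4% in the brain control and 9.07 to 25.0% in the brain knockout, and some of them turned the order of the cord libraries. The myelinating share of the cord control and knockout was 54.6% and 53.4% without a filter, 55.2% and 57.0% at resolution 0.6, and 56.4% and 58.4% with unnamed barcodes counted as myelinating, so the cord gap depends on these choices. Over 10 settings this share ran from 31.6 to 56.4% in the cord control, 48.9 to 67.1% in the cord knockout, 20.1 to 29.8% in the brain control and 20.9 to 35.4% in the brain knockout.

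**Figure D4:**
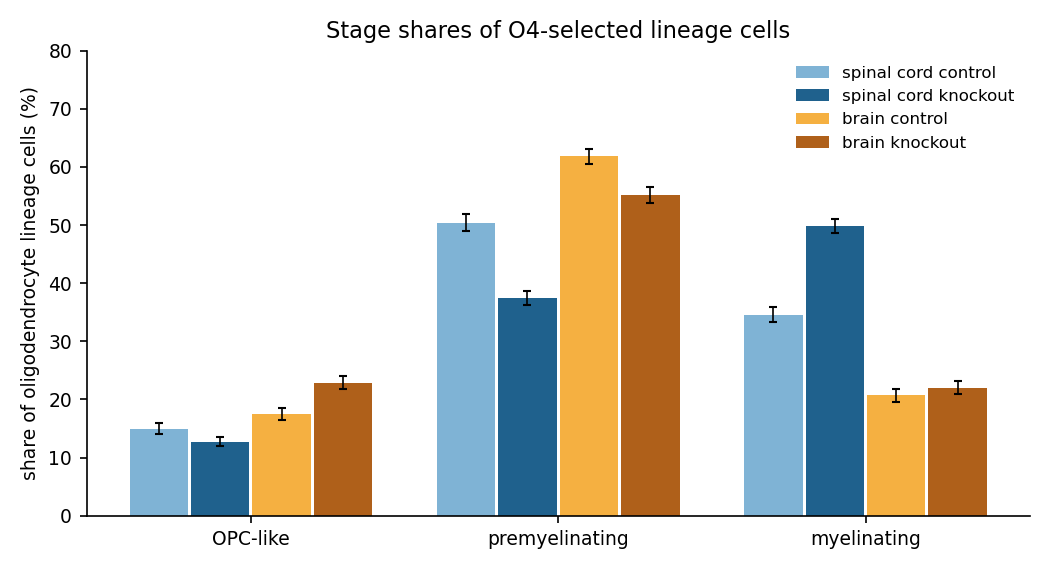
Share of oligodendrocyte-lineage cells in percent that were OPC-like, premyelinating or myelinating in each of the 4 libraries, with bars for shares and lines for 95% Clopper-Pearson intervals. Myelinating cells make up 49.8% in the cord knockout and 34.6% in the cord control, a gap that shrinks to about 2 points or turns in 3 of 10 other settings, and 22.0% and 20.7% in brain, where the order turns (21.5% and 21.9%) with each library clustered on its own.

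Outside the 3 stages, cholesterol genes were lower in cord knockout astrocytes (−0.51, −0.63 to −0.39; 6 of 20 lower) and in cycling cells (−0.43, −0.69 to −0.13), whose main cord cluster held OPC markers, but not in brain knockout astrocytes (−0.03, −0.12 to 0.05). Once free RNA was taken away the cord astrocyte median was −0.0221 (−0.39 to 0.18). The myelin protein list was also lower in cord knockout astrocytes (−0.82, −0.90 to −0.79), cells that do not make myelin. Mtor in astrocytes stood at 23.1 and 19.9 CPM in cord and at 15.1 and 12.6 CPM in brain.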

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

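All tests were chosen after the patterns had been seen, and those of free RNA, of abundant RNAs and of astrocytes only after the result was seen, while those of mixed sexes, of length and GC content, of cell mix and of UMIs per cell were written down before their own values were known. The test of length and GC content took the place of a free RNA test of the brain control's OPC-like cells after that result had been seen, a log2 ratio of the summed list of −2.63 (−2.74 to −2.52) against −2.25 (−2.40 to −2.10) in macrophage-lineage cells.

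A rule was applied to 59 pairs of gene list and stage. It asked for knockout ratios on opposite sides of 0 in the 2 regions, beyond the counting interval of each. It also asked for a regional difference of at least 1.5-fold. The rule was met by 3 pairs, and these differences were not tested. Pairs that differed by less, such as ribosomal protein genes in OPC-like cells, are not counted. Ribosomal protein genes in myelinating cells differed by 0.87 between cord and brain (0.84 to 0.90 over 88 genes), with 0.70 in cord and −0.18 in brain. The brain side was not particular to myelinating cells. In the brain knockout library the list also stood at −0.12 in astrocytes, −0.21 in cycling cells and −0.33 in microglia, while unnamed barcodes stood at 0.17. Interferon and MHC class I genes in premyelinating cells differed by −0.72 (−1.20 to −0.46 over 9 genes), with −0.38 in cord (−0.59 to −0.17) and 0.37 in brain (0.16 to 0.60). Myelin protein genes in OPC-like cells differed by −0.66 (−0.81 to −0.51 over 11 genes), with −0.55 in cord and 0.07 in brain (0.01 to 0.32). Mbp stood at 63911 and 43768 CPM in these OPC-like cells of the cord control and knockout and at 55012 and 39562 CPM in macrophage-lineage cells, and the myelin list at −0.82 in cord astrocytes, so free RNA stays open for this difference.

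Cholesterol biosynthesis genes were lower in the cord knockout library than in the cord control, with a median of −0.60 in myelinating cells. There the summed list was lower by 3248 CPM (3176 to 3322), against 1640 CPM (1247 to 2038) in macrophage-lineage cells, so free RNA falls short as the whole source, and mixed sexes in the control fall short too, since cells with a Y-linked UMI and no Xist UMI gave −0.58 (−0.62 to −0.53). Between myelinating cells of like UMI totals the list median was −0.63 at 2000 to 4000 UMIs (194 control and 1674 knockout cells). At 4000 to 8000 UMIs it was −0.45 (1410 and 1267 cells). Fewer UMIs per cell in the knockout may thus account for part of the myelinating difference, which was not tested. In OPC-like cells free RNA could account for the difference, because the log2 ratio of the summed list, −0.73 (−0.81 to −0.66), lay no lower than the −0.90 (−1.13 to −0.67) of macrophage-lineage cells. A difference across the whole library cannot be told apart from one in the lineage, as the astrocyte median of −0.51 became −0.0221 once free RNA was taken away, with an interval of −0.39 to 0.18 that lies above the myelinating median but reaches too far below 0 to set aside a smaller difference across the library. The loss of mTOR, which the design names, also stays open and untested with 1 library per group. It cannot be told apart from Cre at the Cnp locus, which only the knockouts carried.

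Cholesterol biosynthesis genes were lower in the brain control than in the cord control, the same cord library as in the pattern above, although the knockout libraries differed in the same direction (−0.27 in myelinating cells relative to all genes). Leaving Malat1, Ttr and haemoglobin out of the totals moved the median over all genes in myelinating cells from −0.72 to −0.23. That of the list moved from −1.50 (−1.58 to −1.39) to −1.01 (−1.09 to −0.90). These RNAs thus account for part of the difference in CPM and not for the whole. The step rescales all genes alike, so it cannot change the list relative to all genes and says nothing about that value. Set against genes of like length, GC content and expression, the list stood at −0.90 (−1.01 to −0.82), where relative to all genes it stood at −0.79, which argues against length and GC content. A difference across all cells of the libraries cannot be told apart, since astrocytes after removal of free RNA stood at −0.58 relative to all genes with an interval of −0.72 to −0.03. Region, age and library go together in this design, so each may account for it and none was tested apart.

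Ribosomal protein genes were higher in myelinating cells of the cord knockout library, with a median of 0.70 (0.68 to 0.71). A different mix of cells is argued against by medians of 0.55 (0.53 to 0.58) within MFOL-like and 0.73 (0.71 to 0.74) within MOL-like cells. Fewer UMIs per cell are argued against by medians of 0.73 (0.71 to 0.75) and 0.84 (0.80 to 0.87) between cells of like UMI totals. A difference across all cells is argued against by the astrocyte median of 0.12 (0.08 to 0.15), although unnamed cord barcodes, mainly a cluster led by Mbp, stood at 0.33 (0.30 to 0.35). A hypothesis that loss of mTOR may raise these messages in myelinating cord cells stays open, as do differences in preparation, and neither was tested. The former cannot be told apart from Cre at the Cnp locus. The immediate early and dissociation list also stood above 0 (0.67), but whether it marks preparation was not tested.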

How the results depend on the processing

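The settings that subtract free RNA, keep only Y-linked cells, leave out abundant RNAs, take MFOL-like cells alone, leave the cord precursor cluster whole, or count unnamed or cycling barcodes in a class were chosen after seeing the data. Of 157 alternative values of the cholesterol list, 127 lay inside the counting interval of the value reported and 30 outside, and of 38 alternative OPC-like shares 10 lay inside. Of 360 alternative values of named genes 322 lay inside, and of 260 of other lists 216 did. The cord knockout medians stayed below 0 in all settings run, between −0.79 and −0.48 in OPC-like, −0.53 and −0.46 in premyelinating and −0.69 and −0.52 in myelinating cells, and so did brain against cord. For the cord minus brain difference the settings gave −1.07 to −0.47, −0.47 to −0.39 and −0.48 to −0.32. The brain OPC-like median, 0.20, turned negative in 3 of 13 settings, and where no construction is named below the cause was not tested.

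The stricter cell filter gave −0.12 in brain knockout OPC-like cells, −0.67 in cord knockout myelinating cells, −1.82 for brain against cord in premyelinating cells, −0.48 for the regional difference in myelinating cells, and OPC-like shares of 6.67% and 9.07% in the brain control and knockout. It asks for both 1000 UMIs and under 5% mitochondrial counts, and no cord cluster was then named OPC-like. Without a filter the cord myelinating knockout value was −0.52 and brain against cord −1.37, with shares of 12.5% and 15.6% in cord control and knockout and 19.3% in the brain control. Clustering each library alone gave −0.23 in brain OPC-like cells, −0.47 for the regional difference there, and cord shares of 13.5% and 9.90%. Resolution 0.6 gave −0.53 in cord myelinating cells and shares of 11.0% and 11.4% in cord and 21.5% in the brain knockout, and resolution 1.5 gave 16.1% and 20.4% in brain.

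The mean of per-cell CPM gave −0.0183 in brain and −0.64 in cord knockout, for premyelinating and myelinating cells respectively, and −1.81 for brain against cord in premyelinating cells. Thinning gave −0.0172 in premyelinating and −0.35 in myelinating brain cells, −0.69 in myelinating cord cells and −1.84 for brain against cord in premyelinating cells, leaving out 437, 622, 619 and 507 shallow OPC-like cells. Removing free RNA gave 0.59 in brain OPC-like cells, and Y-linked cells alone gave −0.79 in cord OPC-like cells. MFOL-like cells alone gave −0.68 in cord and −1.39 for brain against cord. A minimum of 100 UMIs gave −2.97 for brain against cord in OPC-like cells.

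Brain against cord moved most with scaling. The median of ratios gave −2.32, −1.03 and −0.79 in OPC-like, premyelinating and myelinating cells, and leaving Malat1, Ttr and haemoglobin out gave −2.32, −1.30 and −1.01. Under the median of ratios, which removes the shift over all genes, the direction in myelinating cells turned for the mTOR list (−0.59 to 0.13) and the sex-linked list (−0.60 to 0.11), both past 1.5-fold in CPM. Lists nearer 0 turned as well, those of myelin proteins (to 0.50), transcription factors (0.58), cholesterol transport (0.35), interferon (0.49), immediate early (0.49) and mitochondrially encoded genes (0.18). Immediate early genes also turned with doublets kept (0.75).

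With the precursor cluster whole, the cord shares were 29.8% and 22.0%, and brain against cord in premyelinating cells was −1.72. Counting unnamed barcodes as myelinating gave −0.53 in cord, −0.32 for the regional difference and shares of 9.97%, 10.6%, 16.2% and 19.6%, and cycling clusters as OPC-like gave 16.7%, 14.1%, 19.4% and 25.0%. Doublets kept gave 16.9% and 14.4% in cord and 20.8% in the brain knockout, and list genes kept gave 16.3%, 13.7% and 21.2%. The cord knockout share exceeded the control without a filter, at resolution 0.6 and with unnamed barcodes counted.

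No paired analysis was possible because each group is 1 library. The stricter filter could not be run for the cord OPC-like shares or for the OPC-like cord knockout, brain against cord and regional values. Depth limits OPC-like cells most, with medians of 915, 758, 886 and 1075 UMIs per cell against 5056, 3473, 5036 and 5528 in myelinating cells.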

Other observations

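Outside the oligodendrocyte lineage, the ribosomal protein list had a median below 0 in the brain knockout library in most cell types, although most members differed by less than 1.5-fold. The median log2 ratio was −0.41 in immature neurons (−0.44 to −0.37; 16 of 80 lower by at least 1.5-fold, none higher), −0.37 in endothelial cells (−0.38 to −0.35; 19 of 88 lower, 3 higher), −0.33 in microglia (−0.34 to −0.30; 13 of 86 lower), −0.30 in mural cells (−0.32 to −0.27; 9 of 86 lower, 1 higher), −0.17 in choroid plexus cells (−0.21 to −0.14; 7 of 84 lower) and −0.12 in astrocytes (−0.15 to −0.11; 4 of 87 lower, 2 higher). Erythroid cells stood apart at −0.82 (−0.89 to −0.78), with 62 of 79 lower by at least 1.5-fold, and at −0.05 relative to all genes. Unnamed brain barcodes stood at 0.17 (0.12 to 0.20), and at −0.10 relative to all genes. In cord, astrocytes stood at 0.12 (0.08 to 0.15). Cord cycling cells, which held OPC markers, stood at 0.15 (0.09 to 0.20), and unnamed cord barcodes, mainly a cluster led by Mbp, at 0.33 (0.30 to 0.35). The driver locus gene Cnp was also lower in knockout astrocytes, at 2740 and 921 CPM in cord and at 419 and 238 CPM in brain. Myelinating markers in these astrocytes stood at 39.7% and 27.2% of their library level in cord and at 25.2% and 25.3% in brain. Free RNA was not taken away from these Cnp values and may account for them.

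Cholesterol biosynthesis genes in the brain knockout library stood at −0.64 in fibroblasts (−0.98 to 0.02; 6 of 9 lower, 1 higher), −0.55 in border macrophages (−0.88 to 0.06; 4 of 8 lower, 1 higher), −0.26 in microglia (−0.40 to −0.01), −0.14 in endothelial cells (−0.35 to −0.01), −0.04 in mural cells (−0.25 to 0.25) and −0.25 in choroid plexus cells (−0.43 to 0.01). Erythroid cells stood at −1.30 (−1.54 to −0.95), and at −0.53 relative to all genes. Apoe in brain microglia differed by a log2 ratio of 1.001 between knockout and control (0.93 to 1.08). Schwann-like cells, which myelinate peripheral nerve, numbered 2 in the cord control and 39 in the cord knockout, and immature neurons 368 in the brain control and 739 in the brain knockout.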
